A study of Mus musculus with 16 samples.

How the data were processed

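RNA of the left ventricle of male C57BL/6 mice was profiled at 0h, 3h, 24h and 7d after abdominal surgery under sevoflurane, with 4 libraries per time. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase and made into libraries with a directional NEBNext kit, and the labels give polyA RNA as the molecule. Per the submitters' processing notes, cutadapt and STAR were used with the mouse build mm10; their versions, the counting tool and its strand setting are not given in the sources used here. Without a stated strand setting, antisense and overlapping genes are uncertain, as are genes with near-identical copies. Which column belongs to which library was taken from the time and number in its name, whose prefix differs from that of the sample titles.

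The authors deposited 1 table with raw counts, TPM and FPKM per library for 57143 genes. Raw counts are whole numbers and were not normalized, per the deposited column names and values. The deposited TPM and FPKM were recovered from the counts and the table's gene lengths to within a relative 1e-06. No mitochondrial gene was in the table (0 of the 57143), and 525 genes had no symbol. Of the gene identifiers, 90.7% were found in GENCODE M21 (GRCm38), which gave the coordinates. A count was present in any library for 29424 genes.

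The design was written before the data were examined, for a table of TPM, with a provision to test raw counts with edgeR if the table held them. That provision applied. Genes with a mean TPM of 0.5 or more over the 16 libraries were tested, 16866 in all, which held 99.84% to 99.9% of the counts of each library. Counts were scaled by TMM and tested with edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest, robust, 16 libraries in 1 fit, no replicate block), and p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Comparisons were 3h, 24h and 7d against 0h, the direct comparisons 24h against 3h and 7d against 24h, and any change over time. The 3 comparisons against 0h share their control libraries, so no overlap between them is given. All adjusted p-values of genes come from this fit unless another tool is named. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

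Before the data were examined, 40 gene lists of pathways, cell types and neighbouring tissues were fixed, and the alternatives below were chosen. Lists were tested with camera (preset correlation 0.01) on log2 CPM with a prior count of 2, adjusted over the lists of a comparison, and again with a correlation estimated for each list. Of the calls with the preset correlation, only that of the neutrophil list at 3h held with the estimated one. A further 6 lists (hepatocyte, cholesterol synthesis, peroxisome, lipogenesis, lipolysis and nuclear-retained RNA) were chosen after the data were seen. Named genes were S100a8 and S100a9, the 8 largest rises and 8 largest falls in each comparison to 0h and the 4 and 4 in each direct comparison, and up to 4 members of smallest p for each list described. The rises and falls had to pass the threshold, reach a mean TPM of 2 in a group, have no overlap between the groups' libraries and carry a symbol of a named gene. Genes or lists outside this rule are said to have been chosen after their values were seen. Some genes that meet the rule are not reported here.

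A fold against a group with 0 counts is a lower bound against 3 counts over that group, scaled by library totals. With 1 to 3 counts the ratio carries a 95% counting interval. These bounds and intervals cover counting error only. TPM values are means ± SD over 4 libraries.

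The tests were checked on simulated counts for the 16866 genes, with 67, 67 and 66 genes changed 1.5-, 2- and 4-fold in each comparison. For 3h, 24h and 7d against 0h, edgeR recovered 31.3%, 28.4% and 23.9% of 1.5-fold and 58.2%, 70.1% and 62.7% of 2-fold changes. Of 4-fold changes it recovered 84.8%, 81.8% and 77.3%, and 4.9%, 4.9% and 3.5% of its calls were false. The shares of false calls were 8.7%, 12.8% and 7.2% for DESeq2 and 7%, 4.5% and 3.8% for limma. The limits set for this check were relaxed after the simulated results were seen: the recovery required of 4-fold changes was lowered, and the limit on false calls was applied to edgeR alone. Camera called the 1 shifted list and 0 of the others of 40. The simulated genes varied independently of each other, so this does not show how often camera calls lists of correlated genes. In the measured data 58 of 59 list calls were weaker with an estimated correlation.

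Alternatives chosen before the data were seen were other pseudocounts, filters, units, scalings, variance models and library weights, fits of the compared groups alone, a replicate block and leaving out each library. An exact permutation test for S100a8 and S100a9 and fry for lists were also among them. They had been written for log2 TPM. On counts, those of scaling by median of ratios, filter, robust variance and block were run in edgeR. Those of pseudocount, FPKM, quantile normalization, trend and weights were run in limma and so change the tool too. DESeq2, no TMM, a removed gene-length trend, sets without libraries rich in liver or atrial transcripts, a Myl7 covariate and limma on log2(TPM + 1) were added after the data were seen. No pair of libraries within a group matched within sampling noise (lowest chi-square per degree of freedom 3.87). All 16 libraries were used.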

Results

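The series profiled RNA of the left ventricle of male C57BL/6 mice at 4 times after an abdominal operation under sevoflurane. Its title ties the work to S100A8/A9, calcium-binding proteins abundant in neutrophils, and to heart injury after surgery outside the heart. Libraries fell into the groups 0h, 3h, 24h and 7d, with 4 libraries in each, and all carry the label of surgery, 0h included. Total counts per library (M, mega) averaged 9.90 ± 1.89 M at 0h, 9.34 ± 0.25 M at 3h, 10.2 ± 0.98 M at 24h and 11.9 ± 1.20 M at 7d (mean ± SD, n = 4), with 8.31 M in the smallest library. The labels do not say whether the libraries of a group came from separate animals, so each p-value measures the spread between these samples. On log2 CPM, Pearson's r between libraries across genes, which are not independent replicates, ran from 0.975 to 0.987 within groups and from 0.964 to 0.987 between groups. Of 16866 genes tested, 3484 (20.7%) changed over time by edgeR's quasi-likelihood F test at an adjusted p under 0.05.

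S100a8 and S100a9, the genes named in the title, rose at 3h and 24h, calls that were lost in some of the other fits. S100a8 (ENSMUSG00000056054) measured 2.58 ± 1.76 TPM at 0h and 65.7 ± 43.4 TPM at 3h (mean ± SD, n = 4 each; log2 fold change 4.98, SE 1.01, adjusted p = 0.0157). At 24h it measured 41.8 ± 37.5 TPM (log2 fold change 4.36, SE 1.06, adjusted p = 0.0146). S100a9 (ENSMUSG00000056071) measured 4.46 ± 1.36 TPM at 0h, 161 ± 131 TPM at 3h (log2 fold change 5.33, SE 1.02, adjusted p = 0.0126) and 89.5 ± 69.0 TPM at 24h (log2 fold change 4.50, SE 1.06, adjusted p = 0.0134). At 7d the difference from 0h was not past the threshold for S100a8, at 12.2 ± 10.1 TPM (log2 fold change 2.47, SE 1.27, adjusted p = 0.368), or for S100a9, at 31.6 ± 26.8 TPM (log2 fold change 2.89, SE 1.20, adjusted p = 0.263). For S100a9 at 7d, DESeq2 gave an adjusted p of 0.0119 and a two-sided exact permutation test of log2(TPM + 1) gave p = 0.0286, the smallest that 70 orderings allow. That permutation test also gave p = 0.0286 for both genes at 3h and at 24h, and p = 0.0571 for S100a8 at 7d. Both genes lie on chromosome 3 of GRCm38, S100a8 at 90668978 to 90670035 on the + strand and S100a9 at 90692632 to 90695721 on the - strand. Without 0h replicate 1 the adjusted p was 0.0686 for S100a8 and 0.0504 for S100a9 at 3h, and 0.053 for S100a8 at 24h. With Myl7, an atrial marker, as a covariate it was 0.0515 for S100a8 at 3h, and 0.177 for S100a8 and 0.119 for S100a9 at 24h. The log2 fold changes in these cases, given below, were no smaller than without the covariate. With 24h replicate 3 as the lone 24h library, and without 3h replicate 3, neither gene was called at 24h, in a fit with 1 library there. That library measured 20.3 TPM for S100a8 and 72.0 TPM for S100a9, against at most 4.89 and 6.21 TPM in a 0h library.

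**Figure D1:**
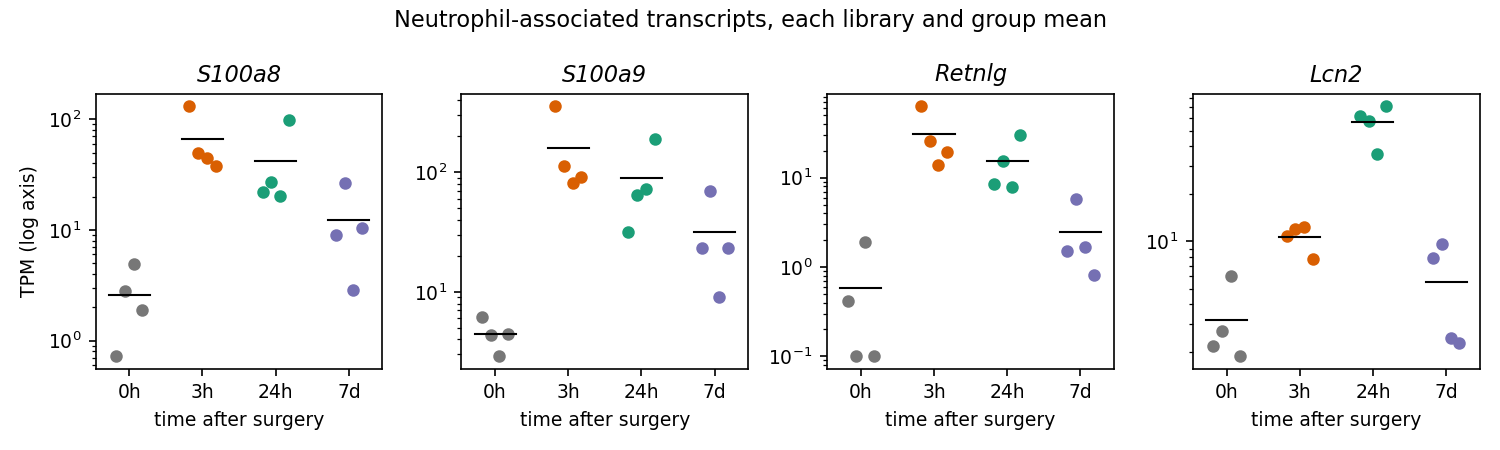
TPM of S100a8, S100a9, Retnlg and Lcn2 in each library (points) by time after surgery, on a log axis, with the group mean as a bar; values below 0.1 TPM are drawn at 0.1 TPM. S100a9 measured 80.8 to 356 TPM in the 3h libraries and 2.89 to 6.21 TPM in the 0h libraries.

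The first comparison set 3h against 0h, shortly after the operation. Retnlg, a resistin-like gene of granulocytes, rose from 0.582 ± 0.906 to 30.5 ± 22.1 TPM (mean ± SD, n = 4 each; log2 fold change 5.91, SE 0.89, adjusted p = 0.00133). Cxcr2, a chemokine receptor of neutrophils, had 3 counts over the 0h libraries and 81 over the 3h libraries, a ratio of 28.6 scaled by library totals (95% counting interval 9.45 to 142, adjusted p = 0.00109). Il1r2, a decoy receptor for interleukin 1, rose from 0.222 ± 0.325 to 2.84 ± 1.47 TPM (adjusted p = 0.0041). Most markers of the fixed neutrophil list were missing or below the filter and were not tested. Genes with few counts at 0h can reach that filter, a mean over all libraries, through the libraries where they are high. Of 12 neutrophil markers measured, 7 were higher and 0 lower over all genes, and 9 were higher when adjusted over the list alone. Their median log2 fold change was 3.44, or 2.08 with 2 genes at their bound (camera, adjusted p = 4.44e-07, and adjusted p = 0.0356 with an estimated correlation). Among these, Mmp8, a neutrophil collagenase, had 1 count at 0h and 69 at 3h (ratio 73.1, interval 12.7 to 2930, adjusted p = 0.0228). Wfdc21 was at least 6.36-fold higher against a floor of 3 counts over the 0h group (adjusted p = 0.0387). Mmp8 was no longer called without 0h replicate 1 (adjusted p = 0.0758), 0h replicate 2 (0.0643) or 3h replicate 1 (0.0817), and Wfdc21 without any 1 of 7 of the 8 libraries (adjusted p up to 0.139). Clec4d, a myeloid lectin at 5.25 ± 3.00 TPM against 0.741 ± 0.0930 TPM (adjusted p = 0.0111), was not called without 0h replicate 1 (0.0575).

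Acute-phase and STAT3 target genes had 13 of 26 measured members higher and 0 lower at 3h, or 16 higher and 1 lower adjusted over the list alone, with a median log2 fold change of 1.34 (camera, adjusted p = 5.41e-13; adjusted p = 0.13 with an estimated correlation). Serpina3n, a secreted protease inhibitor, rose from 14.8 ± 5.57 to 97.7 ± 13.3 TPM (log2 fold change 2.91, SE 0.32, adjusted p = 0.000848). Il4ra, the interleukin 4 receptor alpha chain, rose from 12.4 ± 2.88 to 37.2 ± 4.67 TPM (adjusted p = 0.00046). Bcl3, a nuclear partner of NF-kappa-B, rose from 6.13 ± 0.643 to 22.6 ± 8.83 TPM (adjusted p = 0.0037). The rises of largest fold at 3h included transcripts that are abundant in liver. Fgg, a fibrinogen chain, was at least 21.6-fold higher (61 counts against 0, adjusted p = 0.00451), and Mup3, a major urinary protein, at least 35.7-fold higher (101 counts against 0, adjusted p = 0.0399). Mup3 shares near-identical sequence with its family, so its level is uncertain, and it was not called without any 1 of 7 of the 8 libraries (adjusted p up to 0.0935). The lipoprotein gene Apoa1 had 1 count at 0h and 125 at 3h (ratio 133, interval 23.4 to 5280, adjusted p = 0.000727), and the haem-binding Hpx 1 and 56 (ratio 59.4, interval 10.2 to 2390, adjusted p = 0.0027). Beside these, albumin (Alb) measured 0, 35.6, 28.5 and 5.42 TPM in 3h replicates 1 to 4 and at most 0.281 TPM in a 0h library. A hepatocyte list chosen after the data were seen had 10 of 25 measured members higher at 3h and 20 adjusted over the list alone (median log2 fold change 2.67, also with 7 genes at their bound; camera, adjusted p = 5.02e-14; adjusted p = 0.135 with an estimated correlation).

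Of 28 immediate early genes, 3 were higher and 4 lower at 3h, or 4 and 7 adjusted over the list alone, and the list was not called (median log2 fold change -0.31; camera, adjusted p = 0.18). Among single genes Egr1, an immediate early gene, fell from 49.9 ± 24.1 to 9.68 ± 2.44 TPM (log2 fold change -2.15, SE 0.34, adjusted p = 0.00421). Mycn fell from 5.66 ± 1.72 to 1 ± 0.215 TPM (adjusted p = 0.00971). Sox9 fell from 3.39 ± 0.880 to 0.637 ± 0.408 TPM (adjusted p = 0.00475) and Hic1 from 20.2 ± 3.48 to 5.17 ± 1.97 TPM (adjusted p = 0.00377). Hspa1b, an inducible heat shock protein gene that shares sequence with Hspa1a and is uncertain for that reason, fell from 3.60 ± 0.930 to 0.689 ± 0.316 TPM (adjusted p = 0.00158). Dact2 (log2 fold change -2.27, adjusted p = 0.0108), Egr2 (-1.84, 0.00926) and Cx3cr1, a chemokine receptor (-2.07, 0.0356), were also lower. Without 0h replicate 1 the adjusted p was 0.0643 for Dact2 and 0.0538 for Egr2, and Cx3cr1 was not called without any 1 of the 8 libraries (up to 0.111).

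Glucocorticoid-responsive genes had a median log2 fold change of 0.78 at 3h, with 2 of 24 higher and 1 lower over all genes and 14 higher and 1 lower adjusted over the list alone (camera, adjusted p = 4.9e-07; adjusted p = 0.795 with an estimated correlation). Arrdc2 rose from 18.6 ± 8.60 to 99.9 ± 12.7 TPM (adjusted p = 0.0365) and Rasd1 from 4.58 ± 1.67 to 28.7 ± 10.2 TPM (adjusted p = 0.0397), while the member that fell was Sox9. Neither Arrdc2 nor Rasd1 was called without any 1 of the 8 libraries (adjusted p up to 0.113). Mt2, a metallothionein, measured 197 ± 146 TPM at 0h and 860 ± 174 TPM at 3h (adjusted p = 0.0523). Nuclear genes of oxidative phosphorylation had a median log2 fold change of 0.36, with 2 of 75 higher over all genes and 55 adjusted over the list alone (camera, adjusted p = 4.82e-18; adjusted p = 0.795 with an estimated correlation). The members were Cox5a (1274 ± 78.8 to 1614 ± 94.9 TPM, adjusted p = 0.0369) and Ndufc1 (526 ± 38.6 to 668 ± 50.6 TPM, adjusted p = 0.0426). They were not called without any 1 of 7 (up to 0.114) and of 8 (up to 0.161) of the 8 libraries. Cytosolic ribosomal protein genes, which share reads with pseudogenes, had a median of 0.37, from 0.24 to 0.43 when 1 library was left out (camera, adjusted p = 5.41e-13; adjusted p = 0.795 with an estimated correlation). Of 76, 0 passed edgeR's test over all genes or adjusted over the list alone, 35 had an unadjusted p under 0.05, and DESeq2 called 4 and limma 0. Fatty acid oxidation genes had a median of 0.17, which was -0.03 after quantile normalization and 0.01 by limma on log2(TPM + 1) (camera, adjusted p = 0.0755), with 1 of 30 higher and 3 adjusted over the list alone (camera, adjusted p = 0.00487; adjusted p = 0.795 with an estimated correlation). That member was Plin5, a lipid droplet protein, at 212 ± 22.3 TPM at 0h and 302 ± 42.4 TPM at 3h (adjusted p = 0.0148). Without 3h replicates 2 and 3, the libraries richest in liver transcripts, the list median was 0.14 and not called (camera, adjusted p = 0.0878).

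Extracellular matrix genes had a median log2 fold change of -0.40 at 3h, with 4 of 39 lower over all genes and 7 adjusted over the list alone (camera, adjusted p = 0.00176; adjusted p = 0.795 with an estimated correlation). Fbln2 fell from 62.2 ± 10.8 to 36.9 ± 4.98 TPM (log2 fold change -0.57, SE 0.12, adjusted p = 0.00971) and Fbn1, the microfibril protein fibrillin, from 30.6 ± 8.18 to 14.6 ± 1.75 TPM (adjusted p = 0.0158). Fbn1 was not called without 0h replicate 1 (adjusted p = 0.0608) or 3h replicate 1 (0.0609). The others were Col8a1 (adjusted p = 0.0277, up to 0.103 without any 1 of 5 libraries) and Loxl1 (adjusted p = 0.0387, up to 0.122 without any 1 of 8).

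At 3h, 895 genes (5.3%) changed, 339 higher and 556 lower, and 249 of these differed by a log2 fold change of 1 or more (142 higher, 107 lower). The called count was 298, 437, 496 and 572 without 0h replicates 1 to 4 and 329, 571, 536 and 347 without 3h replicates 1 to 4. It was far larger with array weights or the compared groups alone and smaller with Myl7 as a covariate, values given below. The share of called genes that were higher was 37.9% with TMM scaling, 24.4% without it, 16.8% by limma on log2(TPM + 1), 17.3% with a pseudocount of 0.1 and 50% with a gene-length trend removed. On log2(TPM + 1) the median over all genes was -0.173 at 3h and -0.209 at 24h relative to 0h, so ratios of the printed TPM run below the TMM-scaled fold changes by about that much.

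The comparison of 24h with 0h asked what had changed 1 day after the operation. Slc27a1, a fatty acid transporter, rose from 85.7 ± 5.57 to 177 ± 21.4 TPM (mean ± SD, n = 4 each; log2 fold change 1.27, SE 0.12, adjusted p = 1.54e-06). Cat, catalase, rose from 268 ± 23.9 to 527 ± 25.9 TPM (log2 fold change 1.20, SE 0.12, adjusted p = 3.37e-06). Gclm, a subunit of the enzyme that starts glutathione synthesis, rose from 15.0 ± 3.10 to 38.5 ± 5.20 TPM (log2 fold change 1.60, SE 0.14, adjusted p = 7.66e-07). Tuba4a, an alpha tubulin, fell from 636 ± 109 to 119 ± 48.1 TPM (log2 fold change -2.24, SE 0.20, adjusted p = 1.6e-06).

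Fatty acid oxidation and PPARA target genes had 21 of 30 members higher and 0 lower, or 26 higher adjusted over the list alone, with a median log2 fold change of 0.59 (camera, adjusted p = 1.86e-15; adjusted p = 0.2 with an estimated correlation). Eci2 rose from 105 ± 2.92 to 162 ± 16.1 TPM (adjusted p = 4.68e-05). Acot1 and Acot2, thioesterases that share sequence and are uncertain for that reason, had log2 fold changes of 2.53 (adjusted p = 3.85e-05) and 0.94 (adjusted p = 5.41e-05). NRF2 and antioxidant genes had 17 of 24 higher and 0 lower, or 18 higher adjusted over the list alone, with a median of 0.87 (camera, adjusted p = 1.52e-11; adjusted p = 0.2 with an estimated correlation). Mgst1, a microsomal glutathione transferase, rose from 60.5 ± 6.64 to 318 ± 96.4 TPM (log2 fold change 2.64, SE 0.33, adjusted p = 0.000263). FOXO, autophagy and atrophy genes had 9 of 28 higher and 1 lower, or 11 and 1 adjusted over the list alone, with a median of 0.28 (camera, adjusted p = 0.000161; adjusted p = 0.837 with an estimated correlation). Bnip3, a mitophagy receptor, rose from 357 ± 79.2 to 1629 ± 578 TPM (adjusted p = 0.000826) and Map1lc3b from 118 ± 6.92 to 212 ± 44.6 TPM (adjusted p = 0.000265). Sqstm1, held by both the NRF2 and the FOXO lists, rose from 374 ± 36.7 to 681 ± 149 TPM (adjusted p = 9.02e-05). Fbxo31, a ubiquitin ligase subunit, had a log2 fold change of 1.25 (adjusted p = 1.72e-05).

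Nuclear genes of oxidative phosphorylation had 44 of 75 higher and 0 lower at 24h, or 65 higher adjusted over the list alone, with a median log2 fold change of 0.41 (camera, adjusted p = 1.12e-16; adjusted p = 0.794 with an estimated correlation; adjusted p = 0.0512 after quantile normalization). Ndufa5 rose from 1325 ± 71.2 to 1696 ± 173 TPM (adjusted p = 0.0051) and Uqcrb from 2177 ± 150 to 2808 ± 341 TPM (adjusted p = 0.00561). Tricarboxylic acid cycle genes had a median of 0.17, which was -0.06 by limma on log2(TPM + 1) and -0.15 after quantile normalization, and 4 of 22 were higher both over all genes and adjusted over the list alone (camera, adjusted p = 0.0099; adjusted p = 0.883 with an estimated correlation; adjusted p = 0.159 without 24h replicate 3). The 4 were Idh3g, Idh2, Sdhb and Sdhc, with log2 fold changes of 0.37, 0.38, 0.39 and 0.44. Idh2 and Sdhb were each not called without at least 1 library (adjusted p up to 0.115 and 0.157), and Sdhb was at -0.02 after quantile normalization. Cytosolic ribosomal protein genes had a median of 0.42, with 8 of 76 higher and 0 adjusted over the list alone (camera, adjusted p = 2.37e-10; adjusted p = 0.883 with an estimated correlation; adjusted p = 0.127 after quantile normalization).

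Acute-phase and STAT3 target genes had 11 of 26 higher and 0 lower at 24h, or 12 higher adjusted over the list alone, with a median log2 fold change of 0.75 (camera, adjusted p = 1.25e-06; adjusted p = 0.336 with an estimated correlation). Lcn2, an iron-scavenging lipocalin, rose from 3.20 ± 1.92 to 56.4 ± 15.0 TPM (log2 fold change 4.43, SE 0.46, adjusted p = 6.46e-05). Lrg1 rose from 90.4 ± 4.09 to 298 ± 70.7 TPM (adjusted p = 5.41e-05) and Serpina3n from 14.8 ± 5.57 to 185 ± 53.3 TPM (adjusted p = 1.22e-05). Saa3, a serum amyloid, had 1 count at 0h and 86 at 24h (ratio 83.7, interval 14.6 to 3340, adjusted p = 0.000158). Alb measured at most 0.540 TPM in a 24h library, while the hepatocyte list had 3 of 25 higher and 0 lower at 24h (median 0.98; camera, adjusted p = 0.0434; adjusted p = 0.571 with an estimated correlation). Neutrophil markers had 5 of 12 higher and 0 lower, or 6 higher adjusted over the list alone, with a median of 2.07, or 1.96 with 1 gene at its bound (camera, adjusted p = 0.000947; adjusted p = 0.2 with an estimated correlation). Retnlg measured 15.4 ± 10.1 TPM (adjusted p = 0.00285) and Clec4d 5.11 ± 2.76 TPM (adjusted p = 0.00341). Other large rises were Ccl17, a chemokine (at least 6.81-fold, 21 counts against 0, adjusted p = 0.00659) and Chil3, a chitinase-like protein of myeloid cells (ratio 53.5, interval 9.21 to 2150, adjusted p = 0.00354). Sds, serine dehydratase, rose too (ratio 38.4, interval 10.3 to 323, adjusted p = 5.71e-05).

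Cell cycle genes had a median log2 fold change of -1.02 at 24h, with 4 of 31 lower over all genes and 3 adjusted over the list alone (camera, adjusted p = 0.000175; adjusted p = 0.883 with an estimated correlation; median -0.52 and adjusted p = 0.0605 over genes with a mean TPM of 1 or more, and -0.27 and 0.347 by limma on FPKM). Kif11 fell from 0.868 ± 0.163 to 0.166 ± 0.0899 TPM (adjusted p = 0.0101), and Kif23 from 1.16 ± 0.308 to 0.335 ± 0.128 TPM (adjusted p = 0.0107). Aurkb (adjusted p = 0.0127) was not called without 24h replicate 1 (0.0516), nor Top2a (adjusted p = 0.0489) without any 1 of the 8 libraries (up to 0.121). Antigen presentation genes had 4 of 21 lower both over all genes and adjusted over the list alone, with a median of -0.38 (camera, adjusted p = 0.0153; adjusted p = 0.883 with an estimated correlation). The list was not called without 0h replicate 1 (median -0.26, adjusted p = 0.0773), 0h replicate 3 (-0.18, 0.12) or 24h replicate 3 (-0.31, 0.132), nor by limma on FPKM (adjusted p = 0.0562). Its members Cd74, H2-Aa, H2-Eb1 and Ciita, of the class II pathway, had log2 fold changes of -0.94, -1.10, -1.04 and -1.52, with adjusted p from 0.0238 to 0.0432 and up to 0.136 when 1 library was left out. H2 genes share sequence, so their levels are uncertain.

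Extracellular matrix genes had 5 of 39 higher and 11 lower at 24h, or 5 and 19 adjusted over the list alone, with a median log2 fold change of -0.51 (camera, adjusted p = 0.0132; adjusted p = 0.883 with an estimated correlation; adjusted p = 0.0773 without 0h replicate 1, 0.0699 without 24h replicate 3 and 0.0951 by limma on log2(TPM + 1)). Mmp3, a stromal metalloproteinase, rose from 5.68 ± 3.49 to 38.6 ± 14.6 TPM (adjusted p = 0.000966). Thbs2 rose from 14.0 ± 2.37 to 24.2 ± 3.67 TPM (adjusted p = 0.00468). Lum fell from 125 ± 25.6 to 66.9 ± 13.7 TPM (adjusted p = 0.00289) and Col8a1 from 15.2 ± 3.02 to 8.68 ± 1.69 TPM (adjusted p = 0.00591). Ion channel and calcium handling genes had 6 of 34 lower, with the same count adjusted over the list alone, and a median of -0.27 (camera, adjusted p = 0.00347; adjusted p = 0.883 with an estimated correlation; median -0.1 and adjusted p = 0.102 without 24h replicate 1). With Myl7 as a covariate the ion channel median was -0.14 (adjusted p = 0.261). Camk2d, a calmodulin kinase, fell from 23.7 ± 1.73 to 13.8 ± 3.97 TPM (adjusted p = 0.0017) and Asph from 56.8 ± 3.54 to 32.5 ± 10.1 TPM (adjusted p = 0.0029). With 24h replicate 3 as the lone 24h library and without 3h replicate 3, the ion channel median was 0.25. Interferon-stimulated genes had 2 of 37 higher and 4 lower, with the same counts adjusted over the list alone, and a median of -0.28 (camera, adjusted p = 0.0372; adjusted p = 0.883 with an estimated correlation, up to 0.305 without any 1 of 5 libraries, and 0.114 by limma on log2(TPM + 1)). Iigp1 rose from 32.9 ± 10.5 to 93.4 ± 39.7 TPM (adjusted p = 0.00244), and Gbp3 was lower (log2 fold change -1.03, adjusted p = 0.0187, up to 0.0783 without any 1 of 3 libraries).

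Single genes with large falls at 24h included Apln, the peptide apelin, from 28.3 ± 6.23 to 2.90 ± 1.52 TPM (log2 fold change -3.11, SE 0.45, adjusted p = 0.000726). Upk3b, a mesothelial marker, fell from 2.92 ± 1.66 to 0.119 ± 0.106 TPM (adjusted p = 0.000936), and Sost, the Wnt antagonist sclerostin, from 2.74 ± 1.72 to 0.351 ± 0.189 TPM (adjusted p = 0.00741). Upk3b ran from 0.0817 to 1.64 TPM in the 3h libraries and from 0.0681 to 0.717 TPM in the 7d libraries. Egr1 measured 8.28 ± 2.49 TPM (log2 fold change -2.38, adjusted p = 0.000709), Ces2e 0.523 ± 0.280 TPM (-2.55, 0.0011) and Akap5 0.561 ± 0.291 TPM (-2.45, 0.0111). Mir5107, a microRNA gene whose level is uncertain because it can share reads with an overlapping gene, was at least 2.74-fold lower (0 counts against 8, adjusted p = 0.0356, up to 0.131 without any 1 of 4 libraries).

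Atrial transcripts were higher at 24h, though Myl7, Sln and Myl4 went by library, with 3h replicate 3 high and 24h replicate 3 low. Atrial markers had 6 of 9 higher and 0 lower at 24h, both over all genes and adjusted over the list alone, with a median log2 fold change of 0.81 (camera, adjusted p = 0.00363; adjusted p = 0.2 with an estimated correlation). Myl7, the atrial myosin light chain, measured 63.8, 127, 6.97 and 159 TPM in 24h replicates 1 to 4, 146 TPM in 3h replicate 3 and at most 9.59 TPM in a 0h library. Its call (log2 fold change 5.50, SE 1.44, adjusted p = 0.0175) was lost without 0h replicate 1 (0.0617) or 24h replicate 4 (0.0527). Stard10 (log2 fold change 0.81, adjusted p = 0.00085) and Tbx5 (0.68, adjusted p = 0.0034) were higher in every fit that left out 1 library. Among the gene groups described at 24h, the lone-library fit with 24h replicate 3 gave medians of 0.47 for fatty acid oxidation, 0.50 for NRF2, 0.15 for oxidative phosphorylation and -0.10 for ribosomal protein genes. For neutrophil markers it gave 0.62 against 2.07 with all libraries, and for acute-phase genes 0.24 against 0.75.

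**Figure D2:**
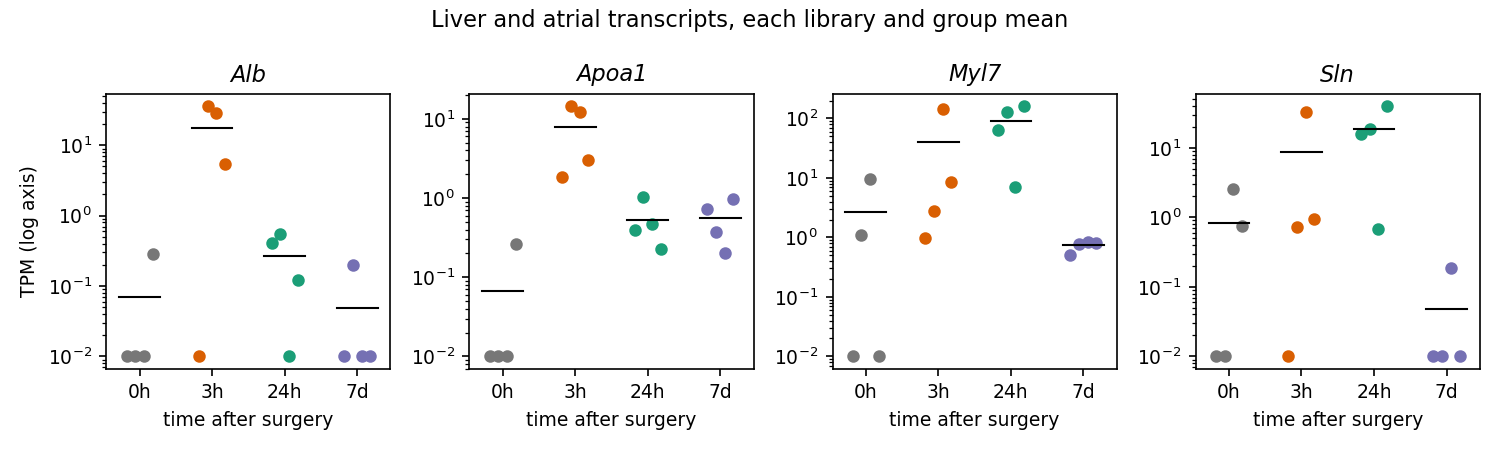
TPM of the liver transcripts Alb and Apoa1 and the atrial transcripts Myl7 and Sln in each library (points) by time after surgery, on a log axis, with the group mean as a bar; values below 0.01 TPM are drawn at 0.01 TPM. Alb reached 35.6 TPM in 3h replicate 2, and Myl7 was 63.8 TPM or more in 24h replicates 1, 2 and 4 and in 3h replicate 3.

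At 24h, 3062 genes (18.2%) changed, 1608 higher and 1454 lower, and 650 of these had an absolute log2 fold change of 1 or more (323 higher, 327 lower). The count was 1796 without 0h replicate 1, 1621 without 24h replicate 1 and 1806 without 24h replicate 4. It was far smaller with Myl7 as a covariate, a value given below with the other processing alternatives. The share of called genes that were higher was 52.5% with TMM scaling, 30.7% without it, 32.5% on FPKM, 18.1% by limma on log2(TPM + 1) and 18% with a pseudocount of 0.1.

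**Figure D3:**
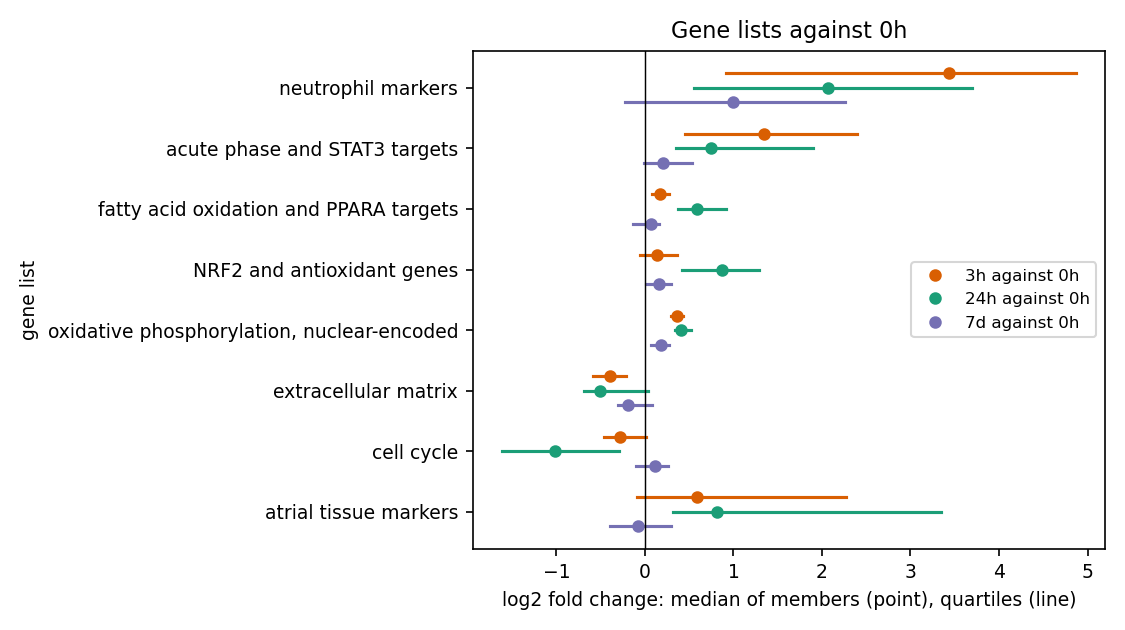
Median log2 fold change (points) and quartiles (lines) of the measured members of 8 gene lists at 3h, 24h and 7d against 0h. The fatty acid oxidation median was 0.17 at 3h, -0.03 there after quantile normalization, and 0.59 at 24h.

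The comparison of 7d with 0h asked what differed between these groups a week after surgery. All comparisons to 0h share its 4 libraries, and no unoperated or time-matched group was profiled. A feature of the 0h libraries can therefore not be told from a lasting change. Egr1 was lower, at 10.2 ± 2.75 TPM against 49.9 ± 24.1 TPM (mean ± SD, n = 4 each; log2 fold change -2.18, SE 0.33, adjusted p = 0.00981). It was as low in the 3h (7.98 to 13.2 TPM) and 24h libraries (6.405 to 11.9 TPM), while the 0h libraries ran from 21.4 to 77.1 TPM. The long noncoding RNAs Lncpint (2.89 ± 0.927 to 0.653 ± 0.140 TPM, log2 fold change -2.01, SE 0.34, adjusted p = 0.00795) and Carmn (2.03 ± 0.0909 to 0.569 ± 0.191 TPM, log2 fold change -1.72, SE 0.31, adjusted p = 0.00905) fell. Alox12, a lipoxygenase, rose from 2.95 ± 0.655 to 6.53 ± 1.23 TPM (log2 fold change 1.21, SE 0.20, adjusted p = 0.00593). These 4 were the only ones of 20 called named genes whose call held in each fit that left out 1 library.

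The other rises by the naming rule were Rasl11b, Yjefn3, Rcor2, Rhd, Mid1ip1, Pdgfa and Phlda1, with log2 fold changes from 0.68 to 1.04, adjusted p from 0.0235 to 0.0432 and up to 0.182 when 1 library was left out. Mid1ip1, a regulator of fatty acid synthesis, measured 142 ± 8.37 TPM at 0h and 233 ± 60.8 TPM at 7d (adjusted p = 0.0268, up to 0.101 without 1 library). Pdgfa, a growth factor, measured 18.9 ± 0.873 and 30.5 ± 3.43 TPM (adjusted p = 0.0235, up to 0.0845). The other falls were Tiaf2, Chac1, Egr2, Zfp169 and Tagap, with log2 fold changes from -2.07 to -1.34 and adjusted p up to 0.155 when 1 library was left out. Chac1, a glutathione-degrading enzyme, measured 11.4 ± 5.51 TPM at 0h and 2.91 ± 0.730 TPM at 7d (adjusted p = 0.0209, up to 0.0779).

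Immediate early genes had 3 of 28 lower at 7d over all genes and 7 adjusted over the list alone, with a median log2 fold change of -0.30, from -0.44 to -0.16 when 1 library was left out (camera, adjusted p = 0.00039; adjusted p = 0.923 with an estimated correlation). Egr1, Egr2 and Klf4 were the 3, of which Klf4 (log2 fold change -0.65, adjusted p = 0.0489) reached 0.167 when 1 library was left out. Klf6 measured 97.0 ± 16.1 TPM at 0h and 65.9 ± 7.23 TPM at 7d (adjusted p = 0.079). Endothelial identity genes had 1 of 23 lower, or 1 higher and 4 lower adjusted over the list alone, with a median of -0.22 (camera, adjusted p = 0.00258; adjusted p = 0.923 with an estimated correlation). That gene was Ptprb, at 64.1 ± 8.80 TPM at 0h and 39.4 ± 10.7 TPM at 7d (adjusted p = 0.0271, up to 0.0993 without 1 library). Glucocorticoid-responsive genes had a median of -0.41 with 0 past the gene test over all genes (camera, adjusted p = 0.00151; adjusted p = 0.923 with an estimated correlation). By edgeR 5 of them had an unadjusted p under 0.05, by DESeq2 1 passed and by limma 0, and Dusp1 had the smallest adjusted p at 0.16 (97.4 ± 32.5 and 57.0 ± 7.21 TPM).

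Unfolded protein response genes had a median of 0.29 at 7d (camera, adjusted p = 0.00198; adjusted p = 0.923 with an estimated correlation; adjusted p = 0.174 without 7d replicate 2). Atf4 was higher (101 ± 5.59 to 131 ± 19.0 TPM, adjusted p = 0.038, up to 0.125 without 1 library) and Chac1 lower. Oxidative phosphorylation genes had a median of 0.18, from 0.12 to 0.23 when 1 library was left out (camera, adjusted p = 1.35e-06), glycolysis and HIF target genes 0.16 (0.00298), ribosomal protein genes 0.23 (1.69e-05), tricarboxylic acid cycle genes 0.11 (0.00908) and NRF2 genes 0.16 (0.047). Each of these 5 had an adjusted p of 0.923 with an estimated correlation and none was called after quantile normalization, where the tricarboxylic acid cycle median was 0. Eno1, of glycolysis, was the 1 member of these lists past the gene test (58.1 ± 7.40 to 71.4 ± 7.10 TPM, adjusted p = 0.0387, up to 0.131 without 1 library). In the other 4 lists 0 members passed edgeR's test. At an unadjusted p under 0.05 edgeR had 15 of 75 for oxidative phosphorylation, 7 of 76 for ribosomal proteins, 4 of 22 for the tricarboxylic acid cycle and 6 of 24 for NRF2. DESeq2 called 2, 0, 0 and 1 of them and limma 0 in each. Without 7d replicate 2 the ribosomal list had an adjusted p of 0.0755, without 7d replicate 4 the tricarboxylic acid cycle list 0.293, and the NRF2 list reached 0.27 without any 1 of 5 libraries.

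At 7d, 189 genes (1.1%) changed, 37 higher and 152 lower, of which 73 had an absolute log2 fold change of 1 or more (7 higher, 66 lower). Of the 152 lower genes, 51 were noncoding, 44 of them annotated as lncRNA or TEC. The count was 53, 50, 35 and 118 without 0h replicates 1 to 4 and 121, 43, 51 and 298 without 7d replicates 1 to 4. The share of called genes that were higher was 19.6% with TMM scaling, 1.9% by limma on log2(TPM + 1), 0% with a pseudocount of 0.1 and 7.7% on FPKM.

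**Figure D4:**
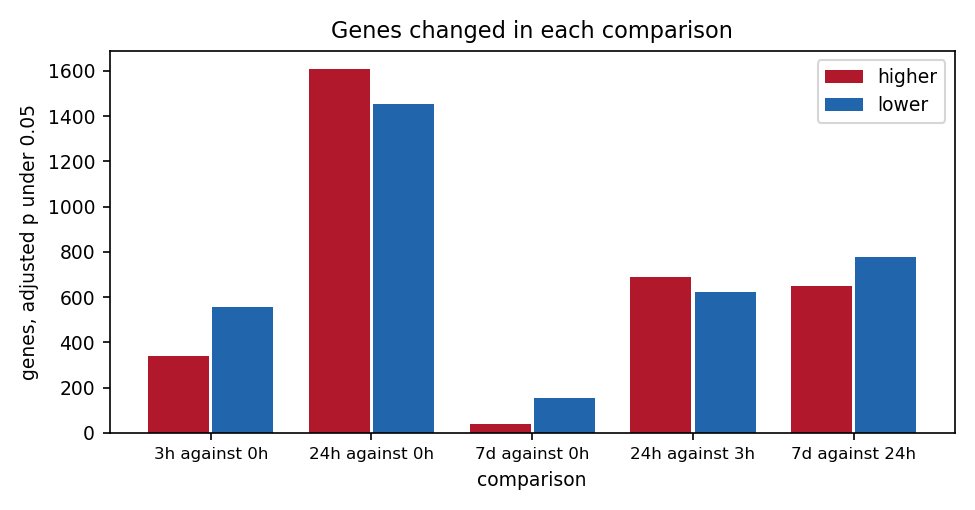
Number of genes with an adjusted p under 0.05 (vertical axis) that were higher (red) or lower (blue) in each of 5 comparisons. The 24h comparison with 0h had 1608 higher and 1454 lower genes, and 7d against 0h had 37 and 152. The share of called genes that were higher at 7d was 19.6% here and 1.9% by limma on log2(TPM + 1).

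The 24h libraries were also set directly against those of 3h. Rnase1, a secreted ribonuclease of endothelium, rose from 0.531 ± 0.267 TPM at 3h to 16.3 ± 7.72 TPM at 24h (mean ± SD, n = 4 each; log2 fold change 4.91, SE 0.60, adjusted p = 1.98e-05). Ppp1r3g, a glycogen-targeting phosphatase subunit, rose from 0.229 ± 0.1 to 2.01 ± 0.984 TPM (adjusted p = 0.00172). Apoa1 fell from 7.89 ± 6.37 to 0.530 ± 0.344 TPM (log2 fold change -3.81, SE 0.64, adjusted p = 0.000627), with the Alb values given above. Cyp1a1, a target of the aryl hydrocarbon receptor, was at least 29.4-fold lower (0 counts against 81, adjusted p = 0.0366). Cxcl5, a neutrophil chemokine, had 1 count at 3h and 49 at 24h (ratio 45.0, interval 7.70 to 1810, adjusted p = 0.0287). Neither held in every fit without 1 library, with adjusted p up to 0.0886 for Cyp1a1 (8 of 8 libraries) and 0.0811 for Cxcl5 (5 of 8). Pvalb (log2 fold change -2.69, adjusted p = 0.017) was not called without 3h replicate 1 (0.088), and Mir5709 was at least 3.63-fold lower (0 counts against 10, adjusted p = 0.0488, up to 0.107 without any 1 library).

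Fatty acid oxidation genes had 13 of 30 higher and 0 lower at 24h against 3h (18 adjusted over the list alone; median log2 fold change 0.39; camera, adjusted p = 1.51e-11; adjusted p = 0.438 with an estimated correlation). NRF2 genes had 12 of 24 higher (14 adjusted over the list alone; median 0.78; adjusted p = 3.23e-09; adjusted p = 0.438 with an estimated correlation). FOXO and autophagy genes had 7 of 28 higher (10 higher and 1 lower adjusted over the list alone; median 0.19; adjusted p = 0.00622; adjusted p = 0.706 with an estimated correlation; up to 0.0785 without 24h replicate 1 or 4). Antigen presentation genes had 5 of 21 lower (6 adjusted over the list alone; median -0.50; adjusted p = 0.000266) and resident macrophage markers 4 of 20 (5 adjusted over the list alone; median -0.30; adjusted p = 0.000723), both at an adjusted p of 0.706 with an estimated correlation. When 1 library was left out, the antigen presentation median ran from -0.64 to -0.25, that of NRF2 genes from 0.49 to 0.90 and that of FOXO genes from 0.08 to 0.26. With 24h replicate 3 as the lone 24h library and 3h replicate 3 left out as well, NRF2 (median 0.11), FOXO (0.08) and atrial (0.41) lists were not called. Cell cycle genes had a median of -0.65 with 0 of 31 past edgeR's test, 7 at an unadjusted p under 0.05, 5 by DESeq2 and 0 by limma (camera, adjusted p = 0.000397; adjusted p = 0.706 with an estimated correlation). The median was -0.14 by limma on FPKM (adjusted p = 0.382) and -0.29 over genes with a mean TPM of 1 or more (0.06). Atrial markers had 1 of 9 higher (median 0.73, adjusted p = 0.019; adjusted p = 0.438 with an estimated correlation; 0.0601 without 24h replicate 4). Of the other 3 lists called, glucocorticoid-responsive genes had a median of -0.42 (adjusted p = 0.0225), ion channels -0.18 (0.0195) and complement 0.27 (0.0496). Their adjusted p was 0.935, 0.935 and 0.706 with an estimated correlation and up to 0.349, 0.38 and 0.153 when 1 library was left out. Complement was not called by limma on log2(TPM + 1) (0.0616). With 24h replicate 3 as the lone 24h library and 3h replicate 3 left out as well, the direction turned for ion channels (0.28) and complement (-0.12). With Myl7 as a covariate ion channels (-0.08, 0.199), complement (0.20, 0.199) and atrial markers (0.14, 0.201) were not called.

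Between 3h and 24h, 1313 genes changed, 689 higher and 624 lower, 349 of them by an absolute log2 fold change of 1 or more (171 higher, 178 lower). The count was 821, 789 and 843 without 3h replicates 1, 2 and 3 and 762 without 24h replicate 1, and the share higher was 52.5% with TMM scaling and 41.1% on FPKM.

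The last comparison followed the tissue from 24h to 7d. Cdo1, cysteine dioxygenase, fell from 43.9 ± 36.5 TPM at 24h to 2.80 ± 0.476 TPM at 7d (mean ± SD, n = 4 each; log2 fold change -4.14, SE 0.58, adjusted p = 0.000806). Nmrk2, a kinase of NAD synthesis in muscle, rose from 2.04 ± 0.584 to 14.7 ± 8.68 TPM (log2 fold change 2.67, SE 0.40, adjusted p = 0.000372). Apln rose from 2.90 ± 1.52 to 19.1 ± 12.4 TPM (2.63, adjusted p = 0.00302) and Sost from 0.351 ± 0.189 to 3.21 ± 1.84 TPM (3.11, adjusted p = 0.00336). Cyp1a1 was at least 47.1-fold higher at 7d (165 counts against 0, adjusted p = 0.0117). The atrial genes Myl7, Sln and Myl4 were lower at 7d, at 0.736 ± 0.157, 0.0473 ± 0.0945 and 1.33 ± 0.359 TPM (adjusted p = 0.0175, 0.042 and 0.031; up to 0.0643, 0.127 and 0.0833 when 1 library was left out). Sln had 1 count over the 7d libraries and 347 over the 24h libraries.

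Fatty acid oxidation genes had 17 of 30 lower and 0 higher at 7d against 24h (21 adjusted over the list alone; median log2 fold change -0.50; camera, adjusted p = 4.32e-18; adjusted p = 0.282 with an estimated correlation). NRF2 genes had 13 of 24 lower (15 adjusted over the list alone; median -0.53; adjusted p = 8.7e-11; adjusted p = 0.303 with an estimated correlation). FOXO and autophagy genes had 10 of 28 lower (11 adjusted over the list alone; median -0.40; adjusted p = 7.7e-08; adjusted p = 0.368 with an estimated correlation). Acute-phase genes had 8 of 26 lower (11 adjusted over the list alone; median -0.68; adjusted p = 5.88e-07; adjusted p = 0.309 with an estimated correlation). Neutrophil markers had 3 of 12 lower (5 adjusted over the list alone; median -1.01; adjusted p = 0.0064; adjusted p = 0.309 with an estimated correlation), with a median of -0.11 by limma on FPKM (0.058). Glucocorticoid-responsive genes had 5 of 24 lower (10 adjusted over the list alone; median -0.73; adjusted p = 5.17e-07; adjusted p = 0.489 with an estimated correlation). Cell cycle genes had 6 of 31 higher (11 adjusted over the list alone; median 0.96; adjusted p = 1.13e-05; adjusted p = 0.526 with an estimated correlation). Atrial markers had 4 of 9 lower (7 adjusted over the list alone; median -0.50; adjusted p = 0.00454; adjusted p = 0.303 with an estimated correlation). Oxidative phosphorylation genes had 6 of 75 lower (9 adjusted over the list alone; median -0.24; adjusted p = 4.87e-08; adjusted p = 0.619 with an estimated correlation; 0.0778 after quantile normalization). When 1 library was left out, medians ran from -0.94 to -0.26 for glucocorticoid-responsive, 0.54 to 1.26 for cell cycle, -0.34 to -0.16 for oxidative phosphorylation and -0.56 to -0.26 for FOXO genes. With 24h replicate 3 as the lone 24h library, oxidative phosphorylation (median -0.02, adjusted p = 0.928), neutrophil (-0.28, 0.319) and acute-phase (-0.08, 0.0637) lists were not called.

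The other 10 lists called from 24h to 7d each lost the call without at least 1 library (adjusted p up to 0.317), and each was at an adjusted p of 0.489 or more with an estimated correlation. Medians were higher for resident macrophage markers (0.19), antigen presentation (0.27), interferon-stimulated genes (0.14), fibroblast identity (0.33), ion channels (0.19) and glycolysis (0.23), and lower for adipose markers (-0.72), endothelial identity (-0.23), immediate early (-0.22) and ribosomal protein genes (-0.19). For ribosomal proteins 0 of 76 passed edgeR's test, 6 had an unadjusted p under 0.05, and DESeq2 and limma called 0. Fibroblast identity had 3 of 18 higher (3 adjusted over the list alone), adipose markers 3 of 9 lower (4 adjusted over the list alone) and endothelial identity 6 of 23 lower (1 higher and 7 lower adjusted over the list alone). With 24h replicate 3 as the lone 24h library, immediate early (adjusted p = 0.765), glycolysis (0.912), endothelial (0.912) and adipose (0.765) lists were not called. In that fit ion channels (-0.24, adjusted p = 0.00049) and ribosomal proteins (0.29, 5.45e-06) were called in the opposite direction. With Myl7 as a covariate fibroblast (0.0779), glycolysis (0.219), immediate early (0.237), endothelial (0.241), ion channel (0.298), adipose (0.341) and atrial (0.607) lists were not called.

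Between 24h and 7d, 1424 genes changed, 648 higher and 776 lower, 372 of them by an absolute log2 fold change of 1 or more (138 higher, 234 lower). The count was 774 without 24h replicate 1, 2457 without 24h replicate 3, 843 without 24h replicate 4 and 861 without 7d replicate 4. The share higher was 45.5% with TMM scaling, 58.8% without it, 61.2% on FPKM, 67.1% by limma on log2(TPM + 1) and 67.8% with a pseudocount of 0.1.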

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

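The tests of liver RNA and of induction in the heart for the hepatocyte transcripts, of atrial tissue for the atrial transcripts, and of exchanged labels were chosen only after the result was seen. For the acute-phase list, the fatty acid oxidation list, gene length and other splits of the libraries, the bounds were set after the pattern was seen and before the test was run.

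Tested were 340 groups of 4 libraries, nearly all of named genes, the rest of library totals, TMM factors and Rn18s-rs5 shares. In 30 of them 1 library lay farther from the others than the critical ratio of Dixon's test. Chance gives about 17 for normally distributed values, which unlogged TPM need not be. S100a8 stood out in 3h replicate 1 (130.5 TPM, the others 37.89 to 49.63) and in 24h replicate 4 (97.92 TPM, the others 20.3 to 26.88), and S100a9 in 3h replicate 1 (356.3 TPM, the others 80.84 to 113.5). Cdo1 was 97.79 TPM in 24h replicate 1, Cxcl5 5.77 TPM in 24h replicate 2 and 0.1728 TPM in 3h replicate 2, Myl7 9.589 TPM in 0h replicate 3. Mir5107 was 14.18 TPM in 0h replicate 1 and Lum 46.43 TPM in 24h replicate 1. Ces2e was 1.34 TPM in 0h replicate 4 and 0.1054 TPM in 24h replicate 4, and Dact2 1.176 TPM in 3h replicate 3. Klf6 was 76.72 TPM in 7d replicate 2, Phlda1 39.94 TPM in 7d replicate 1, Tagap 1.092 TPM and Eno1 82.03 TPM in 7d replicate 4, and Fbxo31 82.08 TPM in 0h replicate 3. Among highly expressed genes were Atp5pf 905.2 TPM in 3h replicate 4, Rpl26 1142 TPM in 3h replicate 1, Ldhb 3297 TPM in 0h replicate 1. Ndufc1 was 468.7 TPM in 0h replicate 3, Ndufs7 823 TPM in 0h replicate 4, and Sdhc 603.2 TPM in 0h replicate 2 and 598.4 TPM in 7d replicate 2. Single libraries above 0 among others at 0 were Apoa1 0.2659 TPM in 0h replicate 4, Chil3 0.1529, Hpx 0.1665 and Saa3 0.09574 TPM in 0h replicate 1, Mmp8 0.1333 TPM in 0h replicate 2 and Sln 0.189 TPM in 7d replicate 3. A lone value above 0 has a ratio of 1 whatever its size, so these flags and that of Cxcl5 at 3h were fixed in advance.

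Of 25 hepatocyte transcripts 10 were higher at 3h. In 3h replicates 2 and 3 the constitutive liver genes had a median of 4.37 TPM, and all 18 below 1 TPM at 0h (100%) were higher than in every 0h library. These 2 libraries were picked by their liver transcripts, so neither value alone decides between RNA from liver and induction in the heart. The medians were 0.026, 3.94, 4.79 and 0.871 TPM in 3h replicates 1 to 4 and 0 in the 0h libraries. Of the wider acute-phase and STAT3 list, 13 of 13 risen members kept at least 50% of their log2 fold change without 3h replicates 2 and 3. Of these, 7 stayed past the threshold. The list thus does not rest on those 2 libraries alone. Since 3h replicate 4 (median 0.871 TPM) stayed in that fit, liver RNA is not excluded for the list. For the hepatocyte transcripts, acute-phase induction in the heart as the whole cause is argued against. The constitutive genes, which such induction would not raise, were also higher in 3h replicate 4 (median 0.871 TPM), which was not picked. They stayed low in 3h replicate 1 (0.026 TPM). Liver RNA and another change in the heart are not told apart.

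Of 9 atrial genes 6 were higher at 24h, with 24h replicate 3 apart. The same number, 6, were lowest in that library, but it was picked by its low Myl7, so the count cannot be set against chance. Without Myl7 it was 5 of 8, and atrial tissue and a change in the ventricle cannot be told apart. Atrial tissue as the whole cause of the fatty acid oxidation change is argued against, since its median was 0.54 with Myl7 as a covariate against 0.59 without (camera adjusted p = 1.86e-13). Myl7 measured 6.97 TPM in 24h replicate 3 and 146 TPM in 3h replicate 3. It thus does not follow the 24h group alone, but it is a single marker. An exchange of labels between 24h replicate 3 and 7d replicate 2 is argued against, since over 2927 genes 64.2% in 7d replicate 2 lay nearer its own group, against 35.3% in 24h replicate 3. A single wrong label, or a weaker response in that heart, may explain it and was not tested.

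Oxidative phosphorylation genes had 2 of 75 higher at 3h and 44 at 24h, and the list was not called with an estimated correlation (adjusted p = 0.795 and 0.794). With a trend on gene length removed from each library, the median was 0.21 against 0.36 at 3h (camera adjusted p = 1.99e-12) and 0.30 against 0.41 at 24h (2.02e-12). Both lay between the bounds set before the test, so the share that gene length could hold cannot be told apart from a change of these genes, while length as the whole cause is argued against. Medians of the ribosomal protein and matrix lists also shrank with that trend removed. At 3h and 24h they were 0.24 and 0.27 for ribosomal protein genes and -0.29 and -0.37 for matrix genes. These lists stayed called by camera with the preset correlation. A change in the tissue with time after surgery stays open and was not tested further.

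For the counts over time, against 0h and of 24h against 3h, only 1 split of the same libraries, the real one, gave as many. A rank of 1 in 35 or in 100 is the best these splits allow, so chance is less likely but not excluded. Mixed splits place differences between times within their groups, which lowers their counts, so the margin adds little. Over time the real count was 3484 and the highest of the others of 100 was 7. Of 35 splits each, the real and highest other counts were 895 and 1 at 3h, 3062 and 20 at 24h, 189 and 2 at 7d, and 1313 and 75 for 24h against 3h. For 7d against 24h the real count was 1424 and the highest other 1417, from the split that exchanges 24h replicate 3 and 7d replicate 2, which points to a structure of the samples. Only 1 of the 35 splits, the real one, reached 1424, and by a small margin, so chance is not excluded here either.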

How the results depend on the processing

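DESeq2, no TMM, the length trend, the sets without several libraries, the Myl7 covariate and limma on log2(TPM + 1) were chosen after the data were seen. The other alternatives were chosen before, and the cause of a change was not tested except where fewer libraries were used. Values are counts of changed genes unless named. An absolute log2 fold change of 1 or more left 249 genes at 3h, 650 at 24h, 73 at 7d, 349 for 24h against 3h and 372 for 7d against 24h. At 7d the count was 27 with a pseudocount of 0.1, 289 with no filter, 39 on FPKM and 35 after quantile normalization. It was 72 by limma without trend, 53 by limma on log2(TPM + 1), 344 with the groups compared alone and 478 by DESeq2. S100a9 at 7d was 2.94 by DESeq2 (adjusted p = 0.0119) and 2.26 in the exact permutation test (p = 0.0286, the smallest that 70 orderings allow). At 3h it was 2671 with array weights, 3193 with the groups compared alone, 1415 by DESeq2 and 596 with the length trend removed. For 24h against 3h it was 773 by limma without trend, 866 with array weights and 835 with the groups compared alone. For 7d against 24h it was 886, 891 and 371. Lists called were 11 at 3h with no filter, 9 at 24h on FPKM and 3 at 7d after quantile normalization. With an estimated correlation 1 list at 3h and 0 in the other comparisons were called, and fry called 3, 7, 0, 4 and 6 in the 5 comparisons. Without 3h replicates 2 and 3 the counts were 321 at 3h, 87 at 7d and 336 for 24h against 3h. A set without 3h replicate 3 and 24h replicates 1, 2 and 4 assumes that the lone 24h library varies like the other groups. Its counts were 1928 over time, 1763 at 3h, 119 at 24h, 456 at 7d, 490 for 24h against 3h and 59 for 7d against 24h. Lists were 24 and 17 for 24h against 0h and 3h. S100a8 and S100a9 at 24h were 3.17 (adjusted p = 0.439) and 4.04 (0.29). That set reversed, at 24h, Mmp8 (-1.61), Jph2 (0.01), ion channels (0.25) and ribosomal proteins (-0.10). It also reversed, against 3h, ion channels (0.28) and complement (-0.12), and at 7d against 24h ion channels (-0.24) and ribosomal proteins (0.29). With the Myl7 covariate counts were 985 over time, 207 at 3h, 113 at 24h, 558 and 29 for the direct comparisons, with 12 lists for 7d against 24h. S100a8 at 3h and 24h was 5.01 (0.0515) and 4.45 (0.177), and S100a9 at 24h 5.25 (0.119). Quantile normalization reversed Sdhb (-0.02) and the tricarboxylic acid cycle (-0.15) at 24h and the latter at 7d (0).

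Leaving out 1 library at a time gave 2521 to 4802 genes over time, 298 to 572 at 3h, 1621 to 4352 at 24h, 35 to 298 at 7d, 762 to 1683 for 24h against 3h and 774 to 2457 for 7d against 24h. Lists called ran from 7 to 9, 12 to 17, 7 to 11, 7 to 13 and 15 to 20. S100a8 ran from 4.33 to 5.44 at 3h, 3.43 to 4.82 at 24h and 1.68 to 2.93 at 7d. S100a9 ran from 4.50 to 5.57, 3.73 to 4.79 and 2.05 to 3.20. Of named genes called, 16 of 30 at 3h, 46 of 66 at 24h, 4 of 20 at 7d, 4 of 8 and 5 of 8 in the direct comparisons never lost the call.

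The replicate numbers did not pair the libraries: of 24 same-number pairs 0 had r over 0.1 (range -0.12 to 0.06), and 0 libraries correlated best with their own number. With the replicate number as a block, 94 genes were called at 7d against 189 without, 26 of 171 named genes were weaker and 59 of 59 lists kept their result. At this depth, genes near the filter rest on few counts, and a difference that missed the threshold is not shown to be absent.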

Other observations

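The lists and genes of the first 2 paragraphs were chosen after their values were seen, except for the 40 fixed lists. Pnpla2, the triglyceride lipase of lipid droplets, rose from 352.8 ± 36.9 TPM at 0h to 915 ± 25.7 TPM at 24h (n = 4 each, log2 fold change 1.60, SE 0.13, adjusted p = 2.14e-07) and was lower at 7d than at 24h (log2 fold change -1.46, adjusted p = 5.24e-07). Lipe, hormone-sensitive lipase, rose from 35.4 ± 7.67 to 55.2 ± 8.65 TPM (adjusted p = 0.000423). Of 16 lipolysis and lipid droplet genes 7 were higher at 24h, 9 adjusted over the list alone (median log2 fold change 0.46; camera adjusted p = 0.000101; adjusted p = 0.0673 with an estimated correlation). At 3h 4 of the 16 were higher (median 0.15; camera adjusted p = 0.00841; adjusted p = 0.176 with an estimated correlation). Of 39 peroxisome genes 15 were higher and 1 lower at 24h (median 0.22; camera adjusted p = 1.88e-05; adjusted p = 0.0673 with an estimated correlation). Ephx2, a soluble epoxide hydrolase, rose from 320.4 ± 28.1 to 564 ± 59.6 TPM (adjusted p = 2.39e-05) and Nudt7 from 39.4 ± 2.06 to 67.4 ± 6.31 TPM (adjusted p = 1.11e-05). The peroxisome list was also called at 3h and 7d (camera adjusted p = 0.0222 and 0.00109; adjusted p = 0.358 and 0.205 with an estimated correlation). There 0 of 39 passed edgeR's test, 6 and 5 had an unadjusted p under 0.05, DESeq2 called 1 and 0 and limma 0. Cholesterol synthesis and lipogenesis genes were not called at 24h (camera adjusted p = 0.904 and 0.332). Cholesterol synthesis was called at 7d (median 0.13; camera adjusted p = 0.0147; adjusted p = 0.239 with an estimated correlation), where 0 of 24 passed edgeR's test, 4 had an unadjusted p under 0.05, and DESeq2 and limma called 0. Hepatocyte transcripts had a median of -2.99 at 24h against 3h, with 11 of 25 lower (camera adjusted p = 1.13e-06; adjusted p = 0.246 with an estimated correlation), while against 0h the 24h median was 0.98 (camera adjusted p = 0.0434; adjusted p = 0.571 with an estimated correlation).

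Of 16 nuclear-retained RNAs 6 were lower at 7d than at 0h and 0 higher (median log2 fold change -0.29; camera adjusted p = 3.75e-05; adjusted p = 0.0979 with an estimated correlation). At 24h against 0h 6 were lower as well, or 8 adjusted over the list alone (median -0.49; camera adjusted p = 0.0143; adjusted p = 0.245 with an estimated correlation). Kcnq1ot1, an imprinted antisense RNA whose level is uncertain without a stated strand setting, fell from 0h to 7d from 0.842 ± 0.0582 to 0.309 ± 0.0408 TPM (log2 fold change -1.35, SE 0.17, adjusted p = 0.000922), and Malat1 from 1425 ± 86.9 to 762 ± 109 TPM (adjusted p = 0.0111). The share of counts on the ribosomal RNA gene Rn18s-rs5 ran from 0.7% to 1.246% at 0h, 0.458% to 1.199% at 3h, 0.194% to 0.508% at 24h and 0.394% to 0.81% at 7d. Whether it bears on the lower noncoding RNAs was not tested. Of 21 core clock genes 2 were higher and 1 lower at 24h. Cry2 rose from 16.3 ± 1.60 to 21.8 ± 3.04 TPM (adjusted p = 0.00259) and Rora was lower (log2 fold change -0.35, adjusted p = 0.0315), while the clock list was not called. Camera looks for a shift in a common direction, so members that move in opposite directions can cancel, and a clock change is not excluded.

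The fixed lists not called at any time against 0h had the following camera adjusted p at 3h, 24h and 7d. Among blood and immune cells these were 0.35, 0.712 and 0.729 for monocytes, and 0.274, 0.0906 and 0.39 for resident macrophages. They were 0.32, 0.691 and 0.261 for T and NK cells, 0.32, 0.516 and 0.826 for B cells. They were 0.32, 0.681 and 0.97 for erythroid and 0.849, 0.857 and 0.746 for platelet markers. Receptors of S100A8/A9 and inflammasome genes gave 0.274, 0.693 and 0.432, cytokines and chemokines 0.943, 0.236 and 0.254, and complement 0.943, 0.113 and 0.0744. Core clock genes gave 0.563, 0.464 and 0.729, heat shock 0.185, 0.857 and 0.564, and p53 targets 0.32, 0.693 and 0.0744. Fetal and stretch genes gave 0.32, 0.643 and 0.471, sarcomere 0.371, 0.121 and 0.746, and beta-adrenergic genes 0.192, 0.681 and 0.564. Endothelial activation gave 0.459, 0.681 and 0.254, fibroblast identity 0.18, 0.175 and 0.39, and mural cells 0.274, 0.681 and 0.752. Adipose tissue gave 0.48, 0.501 and 0.261, mesothelium 0.209, 0.857 and 0.826, and skeletal muscle 0.589, 0.565 and 0.432.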
